A study of Mus musculus with 9 samples.

How the data were processed

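Gene expression was measured on 9 Affymetrix arrays, each hybridised with RNA from the urogenital sinus of C57BL/6 mouse fetuses or newborns. The urogenital sinus is the embryonic structure that gives rise to the prostate, the bladder neck and part of the vagina. Per the labels' protocols, pregnant females received bisphenol A (BPA, a plastics monomer with weak estrogenic activity) at 20 µg/kg/day, diethylstilbestrol (DES, a synthetic estrogen) at 0.2 µg/kg/day, or the corn oil vehicle, from embryonic day 13 to 16. Tissue was taken at embryonic day 17 (E17), embryonic day 18 (E18) and the day of birth (P0). The labels state that bladder, urethra, Wolffian duct, seminal vesicle and Mullerian duct were dissected away in males and females alike. RNA was purified on RNeasy columns and labelled with biotin during in vitro transcription, per the labels' protocols.

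The deposited values are probe set intensities on a linear scale. MAS5, the Affymetrix summary method, is named in the submitters' processing notes, and no version or scaling target is given in the sources used here. The table held 45101 probe sets, among them 64 Affymetrix control probe sets, with 0 missing values. The deposited intensities were not scaled to a common level: the mean after trimming 2% at each end ran from 157 on the BPA P0 array to 277 on the DES E17 array. On the BPA P0 array the hybridisation spikes, which are added in a fixed amount, lay -0.73 log2 units from the average of the arrays, and the brighter probe sets, those above the median level, lay -0.63 log2 units from it. The plan, written before the data were examined, had assumed scaled values and listed quantile normalization as an alternative. Because the intensities were unscaled, quantile normalization between arrays became the main setting before any test was run, and the values as deposited became the alternative. The ratio of 3' to 5' signal of Actb control probe sets was between 1.19 and 1.31, and that of Gapdh between 0.752 and 0.859. Among all pairs of arrays, 0 held identical values. The number of arrays limits the precision, and the intensities carry no count depth.

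Normalised signals were transformed as log2(signal + 5.46), the pseudocount being the 10th percentile of all normalised values, so fold changes of dim genes are understated. Probe sets were named from the platform annotation: 34958 had 1 gene symbol, 932 had several and 9211 had none listed. Of the probe sets with 1 symbol, 34754 had an Entrez identifier in the RefSeq gene table (assembly GRCm38.p6), and 0 symbols needed an update. Each of 18194 genes was represented by its single-symbol probe set with the highest mean log2 value over the 9 arrays. Genes at or above the 40th percentile of mean log2 value over all probe sets (5.54, a signal of 41.2) were tested, which left 13400 genes. Other probe sets of a gene can differ from the chosen probe set, and they were not compared for every named gene.

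The design held 3 agents at 3 ages with 1 array for each combination, so an agent's arrays at the 3 ages were the only repeats of that agent. A linear model with age and agent as factors was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), leaving 4 residual degrees of freedom and 6.18 prior degrees of freedom. The residual spread mixes array noise with any response that differs between ages. The labels do not say how many animals or litters contributed to an array, so p-values measure only the spread between these arrays, which may be partly technical. P-values were adjusted by the Benjamini-Hochberg method over the tested genes with a threshold of 0.05. Whether an agent's difference from control changed with age was tested in a model with a linear age term for each agent, which leaves 2 residual degrees of freedom; its coefficient is a log2 difference per age step. Errors given as SE come from the model, and SD values are over the 3 arrays of an agent or of an age.

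Before the data were examined, 27 gene lists were fixed for processes and cell types that fit the tissue and its neighbours, skeletal muscle, skin-type epithelium, gonad and blood among them. Lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, and were adjusted over the lists of a comparison. The camera test compares a list with the other genes, whereas fry asks whether the genes of a list move, on balance, in a common direction. With the estimated correlation, 0 lists passed in any comparison. That setting also uses the few residual degrees of freedom of the fit, so a lost call does not by itself show correlation between genes. Further marker lists (germ cells, Sertoli cells, adrenal cortex, melanocytes, hair follicle, X genes that escape inactivation, oxygen-responsive genes) were written after the tables had been seen, and the closing section gives their values. For an array without a repeat, a list's median was set among 10000 random lists of the same size matched on signal.

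Named genes were chosen by a rule fixed in advance: for each comparison, the 10 genes with the largest increase and the 10 with the largest decrease among those that passed and had the same sign at all 3 ages (or in all 3 agents). Where fewer passed, the places were filled with genes that did not pass, ranked by the smallest of their 3 differences, and these are named as not passing. In each list the tested members with the largest differences were named, and Esr1, Pgr, Krt10, Fos and Esrrg were followed in every agent comparison. Genes brought up for standing apart on an array were chosen after their values were seen.

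The procedure was tested on simulated data with the 13400 genes and 200 changed genes in 20 runs of the comparison of BPA with control. Changes of 1 log2 unit were recovered for 89.2% of genes and changes of 2 log2 units for 99.6%, 6.51% of calls were false, and an unchanged DES group gave 0.45 false calls per run on average. The simulated genes varied independently around their means with the fitted spread, without age effects, age-specific responses or arrays that stand apart. The rates hold for that setting and do not measure power or false calls in the real data. Alternatives were other pseudocounts, the deposited or median-centred values, no filter or a filter at the 60th percentile, other summaries over probe sets, other variance settings, models without age or agent, fits to 2 agents, a coding of P0 against the mean of E17 and E18, and leaving out each array, age or agent. Added after seeing the data were fits without the BPA P0 and DES E17 arrays and without the BPA E18 and BPA P0 arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Samples from postnatal day 1, which the labels mention, were not analysed here.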

Results

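Transcript levels in the urogenital sinus of mice exposed in utero to vehicle, DES or BPA were compared across 13400 genes on 9 arrays. Each of the 3 agents was represented by 3 arrays, collected at E17, E18 and P0. Of the sum of squares between arrays, age accounted for 32.5%, agent for 27.2% and the residual for 40.3%, where random values would give 25%, 25% and 50%. The first principal component held 31.8% of the variance, with the BPA P0 array at 35.5 and the control P0 array at 23.8, while the DES P0 array lay at -4.45, among the prenatal arrays (-12.9 to -4.18).

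The clearest differences were those of age, and they were led by genes of contracting muscle. Between E17 and P0, Myh8, the perinatal myosin heavy chain of skeletal muscle, rose by 2.39 ± 0.19 log2 units (SE), from a mean signal of 212 ± 88.5 to 1068 ± 205 (SD, n = 3 arrays; limma adjusted p = 0.00203). Atp1b4, a muscle-enriched member of the sodium pump beta family, rose by 2.10 ± 0.19, Myl1, a fast myosin light chain, by 1.75 ± 0.25, Smpx by 1.69 ± 0.19 and Myom2, a protein of the sarcomere's M band, by 1.53 ± 0.16. Prr32, Apobec2, Mylpf, Neb and Chil1 rose by 1.36 to 1.51 log2 units. In all, 83 genes differed between P0 and E17, 62 higher and 21 lower at P0, while 2572 genes had an unadjusted p under 0.05. The genes that fell were led by Fendrr, a long noncoding RNA of lateral mesoderm (-1.04 ± 0.16), and Hif3a, a member of the family of oxygen-regulated transcription factors (-1.0 ± 0.16), followed by Rbm12b2, Tbx20, Grin3a, Igf2bp1, D030056L22Rik, Brwd1, Crhbp and Stmn4, which fell by 0.72 to 0.91 log2 units.

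**Figure D1:**
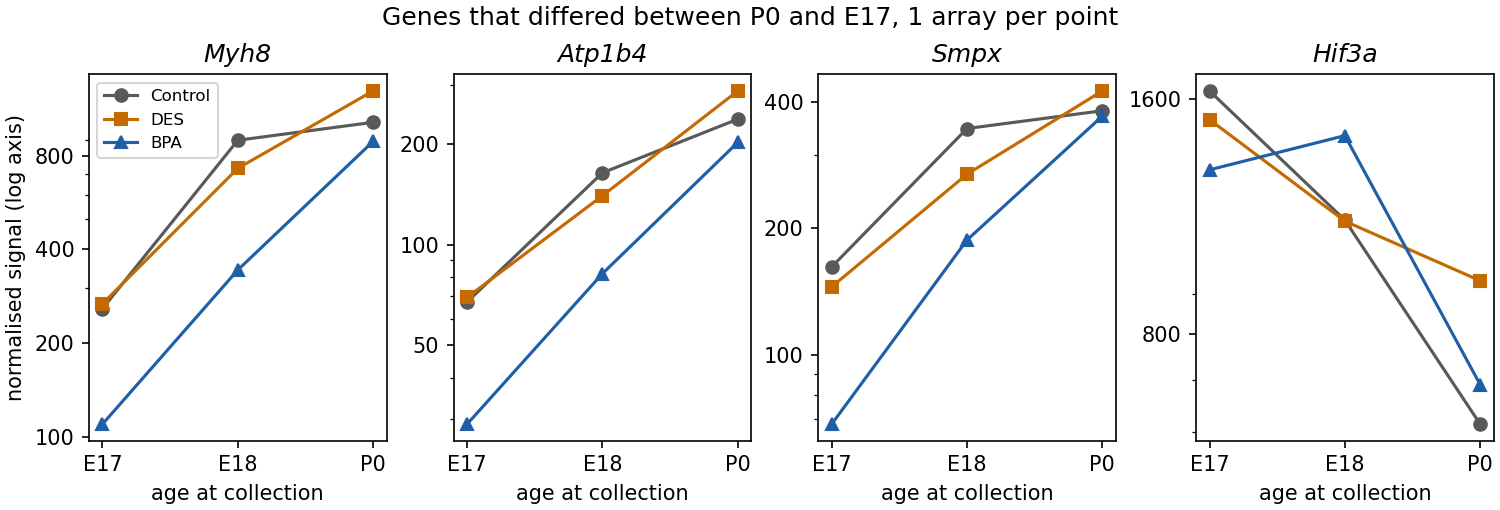
Normalised signal (log axis, arbitrary units) of 4 genes that differed between P0 and E17, against age at collection; each point is 1 array and lines join the arrays of an agent. Myh8 rose from a mean of 212 at E17 to 1068 at P0, and Hif3a fell from 1479 to 747.

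By list, skeletal muscle genes rose between E17 and P0: 21 of 23 tested members were higher, with a median of 0.93 log2 units (camera adjusted p = 8.61e-14). Adjusted over the list alone, 14 passed higher and Acta1 passed lower (-0.40 ± 0.12). With an estimated correlation the adjusted p was 0.246, and with fry it was 0.0261. Cell cycle genes fell, with 23 of 24 lower and a median of -0.18 (camera adjusted p = 2.66e-05, adjusted p = 0.246 with an estimated correlation, and 0.00882 with fry). Bub1 (-0.50 ± 0.12) and Rrm2 (-0.33 ± 0.08) were among the 6 that passed when adjusted over the list alone. Leukocyte genes rose as a list, with 17 of 17 members higher and 1 passing when adjusted over the list alone (median 0.27, camera adjusted p = 2.66e-05 and adjusted p = 0.463 with an estimated correlation). Endothelial genes rose too, with 12 of 14 higher and 1 passing when adjusted over the list alone (median 0.27, camera adjusted p = 0.000385 and adjusted p = 0.246 with an estimated correlation). Fibroblast matrix genes rose as a list, with 20 of 23 higher and 2 passing when adjusted over the list alone, Mfap5 (0.52 ± 0.10) among them (camera adjusted p = 0.000385 and adjusted p = 0.246 with an estimated correlation). Smooth muscle genes fell as a list, with 15 of 17 lower and 8 of them passing when adjusted over the list alone (median -0.35, camera adjusted p = 0.00077 and adjusted p = 0.641 with an estimated correlation). Casq2, the calcium-storage protein of heart and slow muscle, rose by 0.98 ± 0.15 (adjusted p = 0.0267). Xenobiotic metabolism genes rose as a list, with 11 of 13 higher and 3 passing when adjusted over the list alone (median 0.21, camera adjusted p = 0.00328 and adjusted p = 0.463 with an estimated correlation), with Ephx1, an epoxide hydrolase, at 0.77 ± 0.14. The smooth muscle call was lost without the control E17 array and the xenobiotic call without the DES E17 array. All 5 tested erythroid genes were lower (median -1.0, camera adjusted p = 0.0355 and adjusted p = 0.641 with an estimated correlation). Without the BPA P0 and DES E17 arrays the median was -0.07 and the test's direction turned. With values as deposited the median of all genes was -0.29 for P0 against E17, and the medians of the leukocyte, endothelial, matrix and xenobiotic lists were -0.03, -0.02, -0.09 and -0.08, below 0 but above that of all genes, with the camera calls kept. By fry alone, insulin-like growth factor genes were higher (median 0.07) and DNA methylation enzyme genes lower (median -0.24) at P0, at adjusted p = 0.00882 each.

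The count of 83 moved with the arrays used: without the DES P0 array it was 1157, without the control E17 array 6, without the control P0 array 8, without the control E18 array 20, without the DES E18 array 36, without the BPA P0 array 7 and without the BPA E17 array 17. Without all 3 control arrays it was 1, without the BPA P0 and DES E17 arrays together also 1, and with deposited values 723, of which 58 were higher. Among the genes named above, Myh8 passed in 25 of 25 alternatives, Atp1b4 in 22 of 24, Smpx and Myom2 in 21 of 25 each, Prr32 in 19, Mylpf in 17, Myl1 and Apobec2 in 14 each and Neb in 13 of 25. Chil1 passed in 8 of 24, and the genes that were lower at P0 in 7 (Stmn4) to 12 (Hif3a, Crhbp) of 25.

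Between E17 and E18, the same muscle list rose: 21 of 23 members were higher with a median of 0.80 (camera adjusted p = 2.63e-23 and adjusted p = 0.424 with an estimated correlation). Myh8 had a log2 difference of 1.60 ± 0.19 and Tnnt3, fast skeletal troponin T, of 0.97 ± 0.13. Both passed when adjusted over the list alone, but 0 genes passed over all genes in limma (smallest adjusted p = 0.0863, Myh8; 428 genes with an unadjusted p under 0.05, where chance gives 670). Smooth muscle genes fell as a list, with 15 of 17 lower and 0 of them passing when adjusted over the list alone (median -0.25, camera adjusted p = 7.63e-07 and adjusted p = 0.781 with an estimated correlation). This list's call was lost without the control E17 array. Immediate early and stress genes (14 of 20 lower, led by Hspa1a at -0.93 ± 0.35), nuclear receptors (14 of 17 lower) and 3 of 3 tested intestine genes were lower by camera, with adjusted p = 0.0111, 0.0267 and 0.0267, and with an estimated correlation adjusted p = 0.781, 0.701 and 0.701. These calls were lost in 4 of 25, 10 of 25 and 8 of 24 alternatives. The BPA E17 array read 1364 for Hspa1a against 227 to 350 on the others, and the stress gene call was lost without that array. Esr1, the estrogen receptor alpha gene, had a log2 difference of -0.68 ± 0.15 between E17 and E18 (adjusted p = 0.578) and of 0.72 ± 0.15 between E18 and P0 (adjusted p = 0.179).

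Between E18 and P0, cell cycle genes fell as a list, with 24 of 24 lower and 9 passing when adjusted over the list alone (median -0.19, camera adjusted p = 2.54e-07, adjusted p = 0.159 with an estimated correlation, and 0.0179 with fry). Fibroblast matrix genes rose as a list, with 22 of 23 higher and 2 passing when adjusted over the list alone (median 0.11, camera adjusted p = 1.04e-06, adjusted p = 0.159 with an estimated correlation, and 0.0179 with fry). Leukocyte (16 of 17), endothelial (12 of 14), skeletal muscle (19 of 23) and xenobiotic metabolism genes (10 of 13) were higher as lists by camera with adjusted p = 0.000214, 0.00172, 0.00195 and 0.0399. With an estimated correlation the adjusted p was 0.57 for each of these except the endothelial list, at 0.159. The xenobiotic call was lost in 11 of 25 alternatives, and the skeletal muscle call in 3, the fit without the DES P0 array among them. Immediate early and stress genes were higher as a list by camera, with 12 of 20 higher and 8 lower (camera adjusted p = 0.0218 and adjusted p = 0.57 with an estimated correlation), with Atf3 at 0.89 ± 0.17 and Egr1 at 0.74 ± 0.16 among the 5 higher genes that passed when adjusted over the list alone. Hsph1, a heat-shock protein gene, passed lower (-1.09 ± 0.33). That list's call was lost in 5 of 25 alternatives, the fits without the control P0 or DES P0 array among them. By limma 0 genes passed over all genes, with 1918 at an unadjusted p under 0.05. Without the DES P0 array, 511 genes passed. With values as deposited the median of all genes was -0.18, and the matrix, xenobiotic and endothelial medians were -0.03 each, with the camera calls kept.

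The comparison of BPA with vehicle addresses the main question of the series, how BPA exposure in utero alters expression in the urogenital sinus. Fam25c and Fbxo36, an F-box protein gene, were higher after BPA at each age. Fam25c was higher by 1.17 ± 0.13 log2 units, from 213 ± 82.1 in controls to 494 ± 214 (SD, n = 3), and Fbxo36 by 1.11 ± 0.12, from 185 ± 13.8 to 408 ± 69.3 (limma adjusted p = 0.0222 for each). Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, Gsta2, a glutathione transferase, and Cfap57 were higher at all 3 ages by 1.23 to 1.46 log2 units without passing (adjusted p = 0.264 to 0.336). Only Fam25c and Fbxo36 passed over all genes in limma, while 1111 genes had an unadjusted p under 0.05. Over the 25 alternatives the adjusted p ran from 0.0141 to 0.613 for Fam25c, which passed in 13, and from 0.0141 to 0.357 for Fbxo36, which passed in 10. The count was 62 with deposited values, 20 without the control E17 array, 7 without DES E17, 1 without DES E18, 12 without BPA E17, and 12 without the BPA E18 and BPA P0 arrays. No gene passed without a filter or without the control E18, control P0 or BPA P0 array. Without the BPA E18 array 2 genes passed, of which 0 were Fam25c or Fbxo36.

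Genes of squamous keratinisation, the programme of skin-type epithelium, rose after BPA: 14 of 17 tested members were higher (median 0.76, camera adjusted p = 1.29e-08 and adjusted p = 0.332 with an estimated correlation). Adjusted over the list alone, 11 passed and over all genes 0, with log2 differences of 3.4 ± 0.90 for Krt1, 2.31 ± 0.68 for Krt10 and 2.16 ± 0.45 for Lor (loricrin). Flg (filaggrin) read 4.17 to 7.89 on the control arrays, near the pseudocount, and 15.6, 1338 and 2655 on the BPA arrays. The differences lay mainly at the later ages. The median over the list was 0.16 at E17, 0.91 at E18 and 1.17 at P0, and Krt10 had signals of 267, 1253 and 6327 on the BPA arrays against 233, 262 and 277 on the control arrays. Krt4, a keratin of mucosal epithelium, read 1373 to 1964 on the control arrays and 1424 to 1556 on the BPA arrays. Without the BPA E18 and BPA P0 arrays the median was 0.15 (camera adjusted p = 0.0196). On the BPA E18 array the 5 tested erythroid genes were also above the control array, with a median of 1.74, and Alas2, the heme synthesis enzyme of red cells, read 1997 against 297 to 928 on the other arrays. Ivl (involucrin), at 1.22 ± 0.21, and Ly6d, at 1.10 ± 0.22, were higher at all 3 ages without passing over all genes (adjusted p = 0.254 and 0.264).

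**Figure D2:**
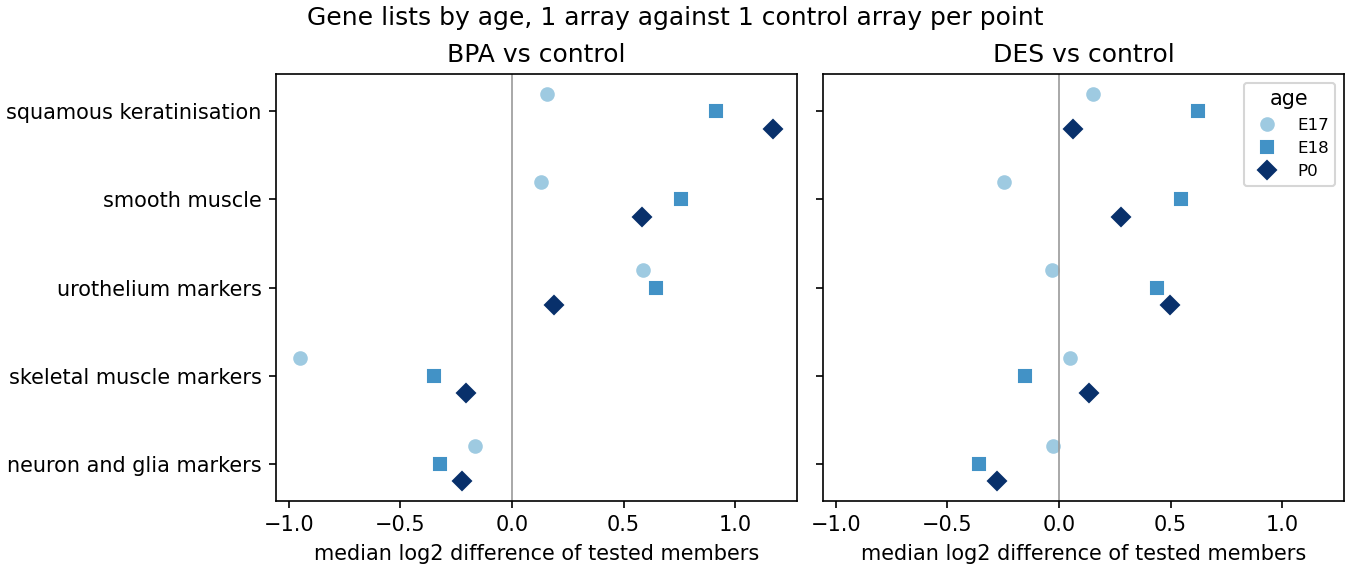
Median log2 difference of the tested members of 5 gene lists between an exposed array and the control array of the same age, for BPA (left) and DES (right); each point is a comparison of 2 arrays. Squamous keratinisation genes had a median of 0.16 at E17 and 1.17 at P0 after BPA, and skeletal muscle genes a median of -0.95 at E17 and -0.20 at P0.

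Smooth muscle genes rose after BPA, 14 of 17 being higher with a median of 0.53 (camera adjusted p = 7.43e-11 and adjusted p = 0.389 with an estimated correlation) and 12 passing over the list alone. Synm (synemin, an intermediate filament protein) had a log2 difference of 1.5 ± 0.30, Cnn1 (calponin) of 0.88 ± 0.17 and Actg2 (enteric smooth muscle actin) of 0.78 ± 0.20. Actg2 read 7163, 3199 and 2955 on the control arrays at E17, E18 and P0, and 7532, 6570 and 7001 on the BPA arrays. Urothelium genes rose as a list, with 9 of 10 higher and 5 passing when adjusted over the list alone (median 0.48, camera adjusted p = 0.000117 and adjusted p = 0.389 with an estimated correlation), with the uroplakin gene Upk3a at 0.62 ± 0.14. Basal and luminal epithelium genes were higher as a list, with 17 of 21 above 0 and 2 passing when adjusted over the list alone (median 0.05, camera adjusted p = 0.0266 and adjusted p = 0.696 with an estimated correlation), with Krt18 at 0.45 ± 0.11 and Krt8 at 0.35 ± 0.09. With values as deposited, where the median of all genes was -0.24, that list's median was -0.18. At E18 its median was -0.05, with 9 of 21 higher. Its call was lost in 7 of 25 alternatives, among them the deposited values and the fits without the control E17, control P0 or BPA E17 array. Estrogen-responsive genes (13 of 25 higher, median 0.03, camera adjusted p = 0.798) and genes of prostate and urogenital sinus development (13 of 26 higher, camera adjusted p = 0.14) did not pass.

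Skeletal muscle genes fell after BPA, 21 of 23 being lower with a median of -0.55 (camera adjusted p = 7.43e-11 and adjusted p = 0.332 with an estimated correlation). Adjusted over the list alone, 10 members passed lower, among them Myh8 (-0.92 ± 0.19) and Ttn (titin, -0.83 ± 0.15), and 2 passed higher, Ckm (muscle creatine kinase, 0.65 ± 0.25) and Acta1 (skeletal muscle actin, 0.41 ± 0.12). The median was -0.95 at E17, -0.35 at E18 and -0.20 at P0. Neuron and glia genes fell as a list, with 15 of 17 lower and 0 passing when adjusted over the list alone (median -0.22, camera adjusted p = 1.27e-06 and adjusted p = 0.332 with an estimated correlation), with Th (tyrosine hydroxylase) at -0.43 ± 0.12. Insulin-like growth factor and endothelial genes, with 9 of 12 and 10 of 14 lower, were lower as lists at camera adjusted p = 0.0487 each (adjusted p = 0.332 each with an estimated correlation). These calls were lost in 17 and 14 of 25 alternatives. Among genes outside the lists that were lower at all 3 ages without passing, Erdr1 had a log2 difference of -2.86 ± 0.47 (adjusted p = 0.224) and Evx1, a homeobox gene, of -0.84 ± 0.16 (adjusted p = 0.264).

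The BPA P0 array carried high signals of gonad genes that were several times lower on each other array. Hsd3b1, a steroid dehydrogenase gene, read 886 there against 4.27 to 10.4 on the other 8 arrays, Amh (anti-Mullerian hormone) 296 against 3.33 to 8.10, and Inha (inhibin alpha) 1813 against 170 to 266. These genes were chosen after their values were seen, and the adjusted p of Inha in the comparison of BPA with control was 0.755. Among 18194 genes, 40 read at least 100 on the BPA P0 array and at least 4 times higher than on each other array, against 2 on BPA E17, 1 on DES E17 and 0 on the others. The 40 include epidermal genes such as Krt10 and Krt1 beside the gonad genes.

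**Figure D3:**
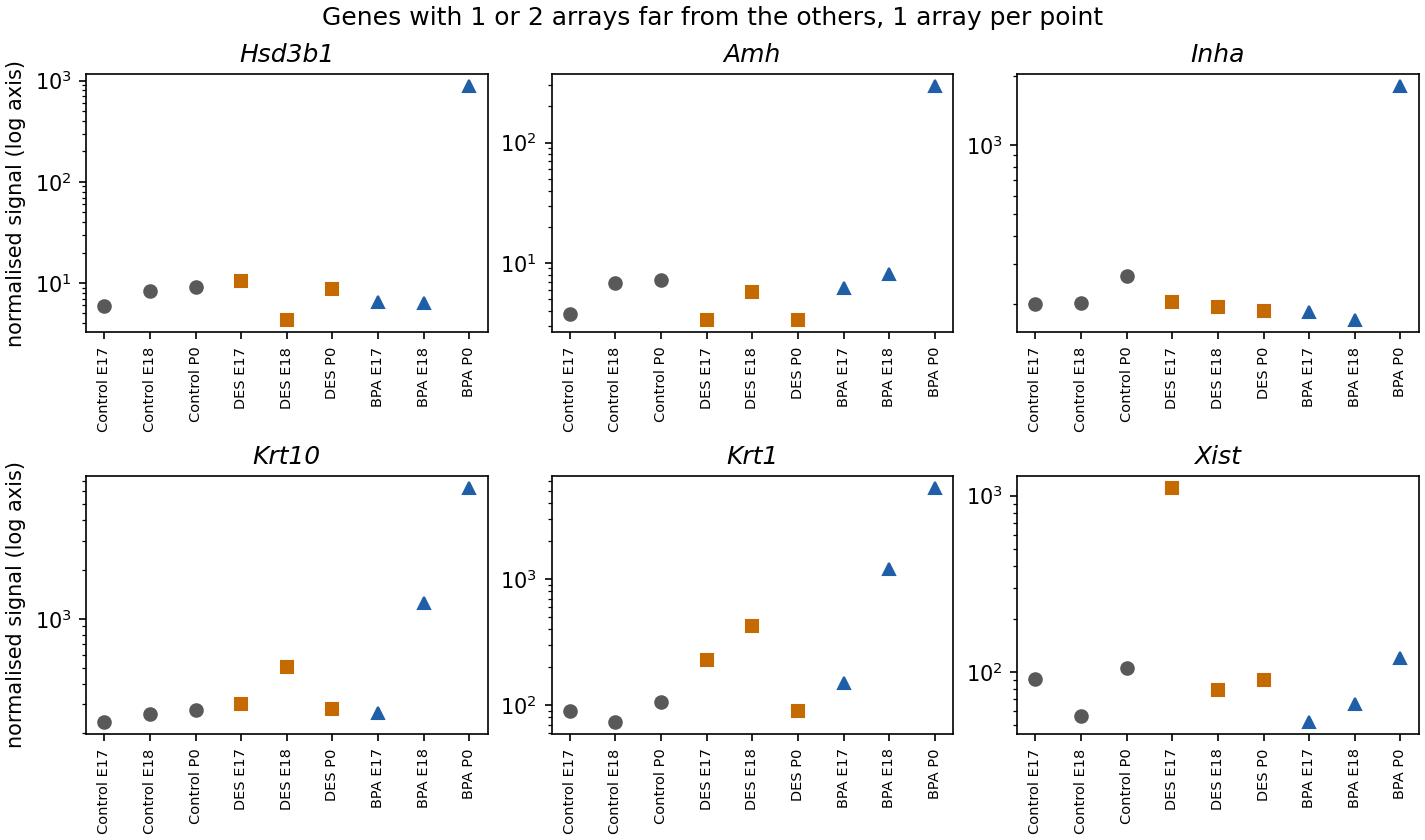
Normalised signal (log axis, arbitrary units) of 6 genes on each of the 9 arrays. Hsd3b1, Amh and Inha stood apart on the BPA P0 array (886, 296 and 1813), Krt10 and Krt1 were highest on BPA P0 and next on BPA E18, and Xist read 1110 on the DES E17 array.

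The comparison of DES with vehicle, which sets a synthetic estrogen beside BPA, gave 0 genes past the threshold in limma (smallest adjusted p = 0.776; 853 genes with an unadjusted p under 0.05). Pgr, the progesterone receptor gene and an estrogen target, had a log2 difference of 0.56 ± 0.18, from 124 ± 18.1 to 185 ± 22.4 (SD, n = 3), and Esr1 of 0.48 ± 0.15 (adjusted p = 0.776 for each). Both were higher at all 3 ages. Rasgrf1 (1.19 ± 0.36), Sprr2f, a cornified envelope gene (1.20 ± 0.41), and Fam167b (1.47 ± 0.36) were higher at all 3 ages without passing, and Erdr1 (-2.35 ± 0.47) and Lpcat4 (-1.31 ± 0.31) were lower without passing.

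Squamous keratinisation genes were higher as a list after DES, with 17 of 17 members above 0 and 0 passing when adjusted over the list alone (median 0.31, camera adjusted p = 0.0145 and adjusted p = 0.532 with an estimated correlation). The median was 0.15 at E17, 0.62 at E18 and 0.06 at P0. The call was lost in 4 of 25 alternatives, among them the fits without the control P0, DES E17 or DES E18 array. Smooth muscle genes were higher as a list, with 16 of 17 above 0 and 0 passing when adjusted over the list alone (median 0.25, camera adjusted p = 0.00092 and adjusted p = 0.564 with an estimated correlation), yet at E17 all 17 were lower, with a median of -0.25. This call was lost in 5 of 25 alternatives, among them the fits without the control E18, control P0 or DES E18 array. Urothelium genes were higher as a list, with 9 of 10 above 0 and 1 passing when adjusted over the list alone (median 0.26, camera adjusted p = 0.00693 and adjusted p = 0.532 with an estimated correlation), with Upk3a at 0.49 ± 0.14. The urothelium median was -0.03 at E17, with 4 of 10 higher, 0.44 at E18 and 0.50 at P0. The urothelium call was lost without the control P0 or DES P0 array. Cell cycle genes were higher in 20 of 24 members, with 0 passing when adjusted over the list alone (median 0.11, camera adjusted p = 0.00719 and adjusted p = 0.532 with an estimated correlation), a call lost in 5 of 25 alternatives. Neuron and glia genes were lower as a list, with 14 of 17 below 0 and 1 passing when adjusted over the list alone (median -0.19, camera adjusted p = 3.4e-06 and adjusted p = 0.395 with an estimated correlation), with Phox2a, a transcription factor of autonomic neurons, at -0.45 ± 0.11. Endothelial genes were lower as a list, with 12 of 14 below 0 and 0 passing when adjusted over the list alone (median -0.13, camera adjusted p = 0.00092 and adjusted p = 0.37 with an estimated correlation). Fibroblast matrix, immediate early and leukocyte genes were lower by camera (adjusted p = 0.0149, 0.0145 and 0.0356), and with an estimated correlation adjusted p = 0.532, 0.532 and 0.59. The leukocyte median was 0.02 at E17, 0.07 at E18 and -0.42 at P0. Without the P0 arrays it was 0.10 with the test's direction turned. That list's call was lost in 5 and turned in 3 of 25 alternatives, the matrix call was lost in 8 and the immediate early call in 4. With values as deposited the matrix median was 0.06 and its call was lost. Estrogen-responsive genes (10 of 25 higher, camera adjusted p = 0.206) and genes of prostate and urogenital sinus development (13 of 26 higher, camera adjusted p = 0.117) did not pass. Of the 9 list calls, 1 was left without the control P0 array. The DES E17 array read 1110 for Xist, the X-inactivation RNA, against 51.8 to 121 on the other arrays.

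When BPA was compared directly with DES, the doses differed by design (20 against 0.2 µg/kg/day) and 0 genes passed in limma (smallest adjusted p = 0.189; 1046 with an unadjusted p under 0.05). Skeletal muscle genes were lower after BPA than after DES in 19 of 23 members (median -0.54, camera adjusted p = 1.41e-10 and adjusted p = 0.517 with an estimated correlation), 14 of them when adjusted over the list alone, with Ttn at -0.91 ± 0.15. Pgr was lower after BPA by a log2 difference of -0.90 ± 0.18 (95% interval -1.31 to -0.50; adjusted p = 0.492), with 97.2 ± 18.3 after BPA and 185 ± 22.4 after DES (SD, n = 3). Pgr passed when adjusted over the list alone for nuclear receptors, at 0.00937. A dimmer Pgr probe set that was not tested read 20.6, 20.1 and 13.3 after BPA at E17, E18 and P0, and 25.25, 16.4 and 17.6 after DES. Its control values were 6.13, 13.5 and 9.37, so on it BPA lay above control at each age and above DES at E18. A further Pgr probe set stayed near the pseudocount (3.45 to 7.2). Squamous keratinisation (12 of 17; median 0.48) and smooth muscle genes (13 of 17; median 0.28) were higher after BPA at camera adjusted p = 8.44e-05 and 6.59e-05, with adjusted p = 0.517 for each with an estimated correlation. Without the BPA E18 and BPA P0 arrays the squamous median was -0.13 and the smooth muscle call was lost. The smooth muscle call was also lost without the DES E17 array, and the squamous call without the P0 arrays. Adjusted over the list alone, 7 squamous genes passed higher and Krt13 passed lower (-0.82 ± 0.28). DNA methylation enzyme genes were lower after BPA in 9 of 10 (median -0.17, camera adjusted p = 0.0321, adjusted p = 0.517 with an estimated correlation, and 0.0298 with fry), with Dnmt3b, a de novo methyltransferase, at -0.42 ± 0.12. None of its members passed when adjusted over the list alone, and the camera call was lost in 13 of 25 alternatives, among them each fit without a DES array. Leukocyte, fibroblast matrix, immediate early and xenobiotic metabolism genes were higher after BPA at camera adjusted p = 0.0132, 0.028, 0.028 and 0.0416, and at adjusted p = 0.517 with an estimated correlation. These calls were lost in 3, 9, 7 and 13 of 25 alternatives. With values as deposited, where the median of all genes was -0.34, the smooth muscle, leukocyte, matrix, immediate early and xenobiotic medians were -0.0042, -0.17, -0.22, -0.20 and -0.25, and the matrix call was lost. The count of genes was 6 without the BPA E17 array, 1 without the control E18 array and 105 with deposited values.

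Across genes, which are not independent replicates, the log2 differences of BPA and DES from the shared controls correlated with r = 0.474. In 100 simulations, all 9 arrays were drawn as unchanged with the fitted spread, and both groups were set against shared simulated controls. There r averaged 0.501 (0.476 to 0.540). The covariance was 0.0228 against a simulated mean of 0.0149 (0.0139 to 0.0164), and 65.8% of genes had the same direction against a simulated 66.6%. The simulated genes varied independently, without arrays that stand apart, so the simulated ranges are narrower than the real arrays allow. Without the control E17 array, r was 0.643. The excess of covariance therefore does not show a response shared by BPA and DES. The controls were not split, since each age had 1 control array.

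The linear age terms asked whether an agent's difference from control changed between E17 and P0. After BPA, 8 genes passed, among them 7 that rose with age. Of these, Krt10 (2.15 ± 0.21 log2 units per age step; adjusted p = 0.0158), Krtdap, Asprv1, Crct1, Kprp, Lce1b and Lce1i are genes of the outer epidermis. Rtp4, an interferon-inducible gene, moved the other way (-1.22 ± 0.14; adjusted p = 0.0212): it read 368, 255 and 204 on the BPA arrays and 145, 262 and 449 on the control arrays. The count was 0 without the control E17 array, 1 without the control P0 array, 125, 123 and 118 without the DES E17, E18 or P0 array, and 82, 93 and 30 without the BPA E17, E18 or P0 array. After DES, 0 genes passed in limma (1198 with an unadjusted p under 0.05). Ndufa4l2, Ppp1r3c, P2rx1 and Slc2a1 shared the smallest adjusted p of 0.297, with coefficients of 0.81 to 1.24. With P0 set against the mean of E17 and E18, 15 genes passed, and without the DES E17, DES E18 or DES P0 array 98, 81 and 13 passed. Without the BPA E17, E18 or P0 array 31, 30 and 31 passed.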

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

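The tests of Y-linked genes, of other DES ages, of Xist probe sets, of the keratinisation medians and of the deposited lists were chosen after the results had been seen, whereas the germ cell and hair follicle tests and the counts of splits were set before theirs were.

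Differences between ages in the response to an agent, by the linear age term, drew attention to the following. After BPA the log2 coefficient per age step was 2.33 for Asprv1, 2.64 for Crct1, 1.79 for Kprp, 2.15 for Krt10, 2.10 for Krtdap, 2.57 for Lce1b, 1.16 for Lce1i and -1.22 for Rtp4. By list, the median per age step after BPA was 0.42 for squamous keratinisation, 0.29 for smooth muscle, 0.32 for skeletal muscle and -0.30 for immediate early and stress genes. After DES it was 0.12 for basal and luminal epithelium, 0.22 for smooth muscle, 0.21 for urothelium and -0.19 for leukocyte genes. With an estimated correlation the adjusted p of these lists was 0.708 after BPA and 0.878 after DES.

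On the BPA P0 array, 10 of 34 gonad or steroid synthesis genes had a probe set of at least 100 that was at least 4 times higher than on every other array, among them Hsd3b1, Amh, Cyp17a1, Nr5a1 and Dazl. The germ cell list, not examined as a whole until its prediction was written, had its median at percentile 100 of matched random lists, with 18 of 19 genes higher. With that median of 1.34 log2 units, the rise was not limited to steroid enzyme genes. The germ cell genes Dazl and Ddx4 were already among the genes that prompted the test, so a rise of this list could be foreseen. It therefore cannot by itself decide on a response of sinus cells without gonad RNA. In the deposited values the median of all 34 genes was -0.08 log2 units from the other arrays, at percentile 100 of random lists of like level, with 15 of 34 higher. Since 10 of the 34 had been picked for reading high there, that percentile cannot decide on lower overall signal of that array. Gonad RNA in that sample is a candidate explanation, which the Sertoli cell list (median 1.41, percentile 100) goes along with, while the adrenal cortex list stood at percentile 75.2 (Cyp21a1 read 105 and Cyp11b1 40.2), and an effect of BPA on gonad cells was not tested.

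Epidermal genes were high on the BPA E18 and BPA P0 arrays, where 13 of 27 squamous list genes on BPA P0 were over 2-fold above each of the 7 remaining arrays. The ratio between the E17 and P0 medians was 0.0712 over all 27 genes with a named probe set (0.16 and 2.21, against 0.16 and 1.17 over the 17 tested members). These values are the same ones that drew attention to the genes, so the ratio cannot decide on a BPA response of equal size at every age. Of the 27 genes, 17 were above control at E17, 21 at E18 and 25 at P0. The member Ivl differed from control by 1.54, 0.91 and 1.22 log2 units at E17, E18 and P0. In the deposited values the 27 genes had a median of 1.97 log2 units from the 7 remaining arrays, at percentile 100, with 19 of 27 higher. Their rise on BPA P0 was thus present before normalization. These 27 include the genes that prompted the pattern, so the percentile cannot decide on lower overall signal of that array. Skin in the samples may be involved, but hair follicle genes stood at percentile 71.5, between the bounds set for and against it, while melanocyte genes, at 33.3, lay below the bound against it, which both lists had to meet. A BPA response that sets in after E17 stays open as well, since each age has 1 BPA array.

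Xist was high on the DES E17 array, where all 3 of its probe sets read more than 4 times the highest other array, which argues against a fault of a single probe set. Xist in DES E18 and DES P0 differed from the control mean by 0.042 log2 units, so a DES response shared by all 3 ages is argued against by the same values that drew attention to Xist, and a response at E17 alone was not tested. RNA of female fetuses is a candidate explanation: the Y-linked genes Eif2s3y, Kdm5d and Uty averaged -0.39 log2 units from the other arrays, though Uty (252) lay within their range (196 to 323). Of the X genes that escape inactivation, 5 of 5 were above the mean of the other arrays (median 0.17, percentile 98.1). Among them, Ddx3x (4341) and 5530601H04Rik (193) lay within the range of the other arrays (3913 to 4809 and 115 to 251). The labels name males and females without giving the sex of a sample.

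For each comparison of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. For P0 against E17 the real split gave 83 genes and the highest other split 0, so that 1 of 10 splits reached the count; for BPA against control the values were 2 and 0, again 1 of 10. For DES against control, BPA against DES, E18 against E17 and P0 against E18, the real split gave 0 genes and the highest other 1, and all 10 splits reached the real count.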

How the results depend on the processing

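Fits without the BPA P0 and DES E17 arrays, and without the BPA E18 and BPA P0 arrays, were chosen after seeing the data; the others were planned. Of 3282 alternative values for named genes, 2950 kept direction and side of the threshold, 252 lost a call, 51 gained a call and 29 changed direction. Of 1123 for called lists, 945 kept both, 173 lost the call and 5 changed direction. Using control arrays alone, 41 of 60 age differences lay within 1 SD of the fitted value. That SD is over the differences of the 3 agents, and the fitted value is their mean with control included. The share therefore cannot show whether the controls alone bear out the fit. The cause of the changes below was not tested unless stated. What signal over background limits is the dim genes: those below a signal of 41.2 were not tested.

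With values as deposited, whose median over all genes moved to -0.24 for BPA against control, 0.11 for DES against control, -0.34 for BPA against DES, -0.29 for P0 against E17, -0.10 for E18 against E17 and -0.18 for P0 against E18, the counts of genes became 62, 1, 105, 723, 8 and 16. Lower genes made up 34 of the 62, 90 of the 105 and 665 of the 723, against 21 of 83 with quantile normalization. The effects by age became 206 for BPA, 178 of them lower, and 36 for DES. Median centring gave 1 gene for E18 against E17.

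The count for BPA against control was 0 without a filter, with every probe set, without a variance trend, without an age term and with 2 agents only. For P0 against E17 it was 8 without a filter, 50 with the mean of probe sets, 25 with every probe set, 6 without a variance trend and 27 without an agent term. The BPA effect by age counted 1 gene without a filter, 4 with the stricter filter, 2 with every probe set and 0 without a variance trend. The DES effect by age counted 15 with P0 against the mean of E17 and E18. List calls for BPA against DES numbered 5 without a variance trend and 4 without an age term. With an estimated correlation 0 lists passed in each of the 6 comparisons, and with fry 0 for BPA against control, 0 for DES against control, 1 for BPA against DES, 6 for P0 against E17, 0 for E18 against E17 and 6 for P0 against E18.

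Without the BPA P0 and DES E17 arrays, P0 against E17 counted 1 gene, E18 against E17 had 9 list calls and the correlation of BPA and DES differences was 0.365. In that fit Esrrg stood at 0.039 for BPA against control, Fos at -0.044 for DES against control and Esr1 at 0.11 for BPA against DES, and the erythroid median was -0.068 for P0 against E17. Without the BPA E18 and BPA P0 arrays, which leaves 1 BPA array assumed to vary like the others, the counts were 12 for BPA against control, 11 for BPA against DES and 6 for P0 against E17, with a correlation of 0.348. Esrrg was then at 0.18 for BPA against control and 0.026 for BPA against DES, Krt10 at -0.22 and the squamous median at -0.13 for BPA against DES.

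The fitted difference of Fos, near 0 in each agent comparison, turned to -0.0049 (larger pseudocount) and -0.039 (median centring) for DES against control. With deposited values it turned to -0.14 for BPA against control and -0.20 for BPA against DES. At E17, E18 and P0, Fos differed from control by 0.74, 0.48 and -0.83 after BPA, and by 0.23, 0.38 and -0.61 after DES. The fitted values near 0 thus average opposite signs. Fos read 218, 207 and 515 on the control arrays. Ctsf turned to -0.32 for P0 against E18 with the mean of probe sets.

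Leaving out each array, age or agent gave ranges of 0 to 32 genes for BPA against control, 0 to 6 for BPA against DES, 1 to 1157 for P0 against E17, 0 to 1 for E18 against E17, 0 to 511 for P0 against E18, 0 to 125 for the BPA effect by age and 0 to 98 for the DES effect by age. List calls ranged from 5 to 8 for BPA against control, 1 to 9 for DES against control, 3 to 9 for BPA against DES, 2 to 9 for E18 against E17 and 4 to 8 for P0 against E18. The correlation ranged from 0.333 to 0.643. Log2 differences that changed sign ranged, for BPA against control, from -0.18 to 0.61 for Fos and -0.42 to 0.064 for Esrrg. For DES against control they ranged from -0.085 to 2.38 for Flg, -0.049 to 1.20 for Krt10, -0.21 to 0.39 for Fos, -0.0092 to 0.32 for Esrrg and -0.23 to 0.10 for the leukocyte median. For BPA against DES they ranged from -0.28 to 0.0053 for Esr1 and -0.12 to 0.45 for Fos. The interaction fits without an array keep few residual degrees of freedom.

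Arrays of different agents were compared within ages, since age is a term of the model. The replicate numbers only name the arrays and pair nothing further.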

Other observations

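Genes known to respond to low oxygen differed by agent in their course from E17 to P0. The list of 28 tested genes was written after 2 of them, Slc2a1 and Vegfa, had been seen, so its tests are not independent of that choice. From E17 to E18, 24 of 28 were lower on the control arrays and 26 of 28 on the BPA arrays (median -0.30 log2 units each), and 16 of 28 on the DES arrays (median -0.02). From E17 to P0, 27 of 28 were lower on the control arrays (median -0.66 log2 units) and 26 of 28 on the BPA arrays (median -0.80), whereas on the DES arrays 18 of 28 were lower and the median was -0.07. Slc2a1, the main glucose transporter of many fetal cells, read 2050 at E17 and 455 at P0 in controls, 2508 and 576 after BPA, and 1751 and 1491 after DES. Ankrd37 read 277 and 44.0, 237 and 68.4, and 201 and 244 in the same order. The linear age term of DES was higher for 27 of the 28 genes (median 0.29 per age step; limma camera p = 1.32e-15, and p = 0.0121 with an estimated correlation). The DES P0 array lay among the prenatal arrays on the first principal component (-4.45), and the labels give no hour of collection. The medians differed at E18 as well. Each median is a change from the agent's own E17 array, so this does not show whether the E17 or the E18 level differed. With 1 DES array at each age, an effect of the agent cannot be separated from differences between single samples.

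The BPA E17 array read 1364 for Hspa1a, a heat-shock protein gene, against 227 to 350 on the other arrays, and 378 for Fabp2, an intestinal fatty acid binding protein gene, against 2.15 to 71.0.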
